A study of Homo sapiens with 12 samples.

How the data were processed

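PolyA RNA of 12 libraries was analysed, 3 each of HL-60 cells carrying the vector or the miR-722 construct, without or with doxycycline (DOX, 1 µg/ml from day 4 of 6 days of differentiation, under 1 µg/ml puromycin). The agent used for differentiation was not named in the labels. The submitters' processing notes named bcl2fastq, STAR 2.5, featureCounts, Subread 1.5.1, edgeR 3.20.8 and the hg38 genome. The strand used for counting was not stated, and 95.7 to 96.1% of exonic reads lay on the strand opposite to the gene.

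The deposited gene table gives raw counts per gene for each library, and 14691 genes were kept in it by a filter whose rule was not stated. The authors also give log2 fold changes of the +DOX and -DOX groups within each line, with the p-value and false discovery rate of an edgeR test that was not specified. The deposited enrichment tables hold each term's number of genes, p-value, false discovery rate and fold enrichment, a ratio of shares of genes. A read summary per library, in numbers and percent of reads, was used for depth and for read kinds. The 12 per-sample columns of log CPM were not used. Raw reads per library numbered 37608139 to 44200278 and table totals 30977995 to 36592278, and 1 CPM on the TMM scale stood for 28.8 to 38.9 counts. The 10 highest genes took 6.5 to 8.2% of the counts.

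Of the 14691 gene IDs, 14637 were found in GENCODE 29, from which gene types and 3' UTRs were taken. Coordinates are those of the gene table (hg38). Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group kept 14682 genes, libraries were scaled by TMM, and all 12 libraries entered a single quasi-likelihood fit with 4 group means and 8 residual degrees of freedom. Pairwise comparisons and the interaction used its F-test with Benjamini-Hochberg adjustment, and genes under an adjusted p of 0.05 are called. SE is the absolute log2 fold change divided by the square root of its F statistic. It restates that test and was not taken from the fit itself. Where a group had 0 counts, the fold is a lower bound from 3 counts over the group; with 1 to 3 counts the ratio is given with a 95% exact binomial interval. Intervals and bounds cover counting error only.

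For 31 gene lists, fixed before the data were examined, limma 3.58.1 camera was run on log2 CPM (prior count 2) with the preset inter-gene correlation of 0.01 and again with a correlation estimated per list, adjusted over the 31 lists of a comparison. With the preset correlation 79 of the 155 list tests were called, and with estimated correlations 2, the actin cytoskeleton in both comparisons of the lines. Members were counted with adjustment over all genes and over the list alone. For 7-mers, the log2 fold change of protein-coding genes was regressed on presence of each 7-mer in the longest annotated 3' UTR (at least 50 bases), with log2 length and A+T share as covariates.

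Genes are named by a rule fixed before the data were examined. Per pairwise comparison, among called genes with a mean of at least 5 CPM in a group and non-overlapping groups, it takes those with the highest and lowest log2 fold changes, 12 per direction for the induction and 6 for the others, and 6 per direction for the interaction. In every list it takes up to 4 members with the lowest adjusted p, and RAC2 always. Clone-style names, XIST and Y-linked genes were left out. The text leaves out some genes that the rule names, and 1 list and some genes are not reported here. The genes of the closing section that were silent in vector -DOX or on in a single library were chosen after their values were seen.

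The steps were tested on simulated data. In libraries drawn with the spread of the real ones and no difference between the groups compared except in planted genes, 24, 72, 88 and 100% of 50 genes each were recovered at 1.25, 1.5, 2 and 4-fold for the miR-722 DOX comparison, with 12 false calls among 14601 genes. For the vector DOX comparison 32, 82, 92 and 100% were recovered, with 8 false calls among 14677. A planted list was called with 0 other lists. Genes were drawn independently of each other there, so false calls of lists through correlated genes could not appear. A 7-mer planted on shuffled fold changes of the vector DOX comparison ranked 1.

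Alternatives were DESeq2 1.42.0, its size factors in edgeR, total counts without TMM, no filter or a stricter filter on low counts (at least 1 CPM in 3 libraries and 50 counts), only the groups compared, the replicate number as a block over all groups or within each line, stricter thresholds, mitochondrially encoded genes left out, and leaving out each library in turn. Leaving out both libraries that stood apart, and the submitters' thresholds, were added after the data were seen. Summaries and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.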

Results

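Messenger RNA was sequenced from differentiated HL-60 cells, a human promyelocytic leukaemia line that takes on neutrophil-like features in culture. The cells carried either an inducible construct for the zebrafish microRNA miR-722 or the vector alone, and each line was grown without or with doxycycline (DOX), 1 µg/ml from day 4 of 6 days of differentiation. This gave 4 groups of 3 libraries. The table of gene counts held 34879373, 35640571 and 36592278 counts in vector -DOX replicates 1, 2 and 3, and 30985307, 31283197 and 33616651 in vector +DOX. It held 33788440, 35338382 and 33511390 counts in miR-722 -DOX replicates 1, 2 and 3, and 33965337, 30977995 and 32191537 in miR-722 +DOX. Between 14293 and 14683 genes had at least 1 count in a given library. The microRNA itself was not measured by these libraries. Whether the 3 libraries of a group came from separate cultures was not stated, so all p-values measure only the spread between these samples, which may be technical. Levels are CPM, counts relative to library sizes scaled by the trimmed mean of M-values (TMM), with the SD of 3 libraries, and log2 fold changes carry their SE.

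The first principal component held 87.9% of the variance and placed every miR-722 library apart from every vector library. Along it the miR-722 -DOX libraries stood between the vector libraries and the miR-722 +DOX libraries. A pair of libraries stood apart from their own groups, miR-722 -DOX replicate 3 (73.0 against 46.1 and 46.1) and vector +DOX replicate 2 (-71.3 against -107.8 and -106.0). Along this component both lay nearer to miR-722 +DOX than the rest of their groups. On the second component (6.7% of the variance) vector +DOX replicate 2 lay at 11.2, against -18.8 and -10.1 in its group. There it leaned towards miR-722 -DOX (39.2 to 50.8) and away from miR-722 +DOX (-32.1 to -28.4). The numbers of changed genes are therefore also given without these 2 libraries.

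**Figure D1:**
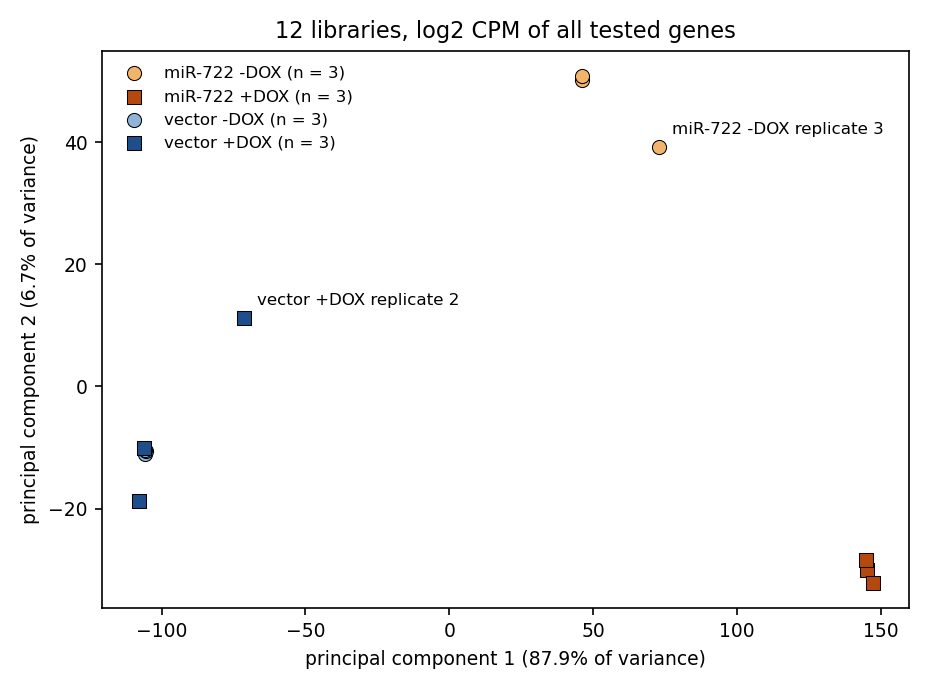
Position of each of the 12 libraries on principal components 1 (87.9% of the variance) and 2 (6.7%) of log2 CPM over all tested genes; colour and shape give the group. The 3 miR-722 +DOX libraries lie at 144.8 to 147.1 on component 1, and the 2 named libraries lie away from the others of their groups.

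The comparison of miR-722 +DOX with miR-722 -DOX asked which transcripts changed when the microRNA was induced in its own line. Of the 31 gene lists, camera called 11 lower and 8 higher with its preset correlation and 0 with estimated correlations. S100A9 (ENSG00000163220.10, chromosome 1, 153357854 to 153361027, hg38), an abundant calcium-binding protein of neutrophils, fell from 2170 ± 503 to 71.7 ± 13.1 CPM (SD, n = 3; log2 -4.92 ± 0.18, adjusted p = 1.53e-09). ITGAM (ENSG00000169896.16, chromosome 16, 31259990 to 31332892), the alpha chain of complement receptor 3, fell from 301 ± 65.7 to 15.4 ± 0.806 CPM (log2 -4.29 ± 0.14, adjusted p = 1.38e-09). MYC (ENSG00000136997.15, chromosome 8, 127735434 to 127741434), a transcription factor that drives growth, rose from 545 ± 158 to 1120 ± 22.7 CPM (log2 1.04 ± 0.14, adjusted p = 4.3e-05).

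Proteins of secondary and tertiary granules, which neutrophils make late in maturation, were the lowest of the called lists. Of 17 measured, 0 rose and 16 fell, with a median log2 of -3.01 (camera adjusted p = 7.99e-07; adjusted p = 0.318 with an estimated correlation). CHI3L1 fell by 2.74 on the log2 scale. S100A8, which the list holds beside S100A9 although both are mainly cytosolic, fell by 4.43. The list is thus not one of granule proteins alone. Among 27 phagocytic receptors 1 rose and 22 fell (median -1.92, camera adjusted p = 3.97e-08; adjusted p = 0.318 with an estimated correlation), with CR1, the receptor for complement C3b, at 11 ± 0.581 against 194 ± 40.4 CPM. Chemoattractant receptors guide neutrophils to sites of infection, and 3 of 24 rose and 18 fell (median -1.58, or -1.45 with 1 member at its bound; camera adjusted p = 3.79e-05; adjusted p = 0.318 with an estimated correlation). The formyl peptide receptors FPR2 and FPR1 fell by 5.35 and 3.87, and the C5a receptor C5AR1 fell from 118 ± 26.3 to 3.28 ± 0.68 CPM. Of 9 subunits and partners of the NADPH oxidase, 0 rose and 7 fell (median -0.80, camera adjusted p = 0.00256; adjusted p = 0.318 with an estimated correlation), among them CYBB (390 ± 65.1 to 105 ± 3.61 CPM) and NCF1 (152 ± 35.8 to 19.6 ± 3.43 CPM). Integrins and adhesion molecules had 4 of 22 risen and 16 fallen (median -0.71, camera adjusted p = 0.000546; adjusted p = 0.318 with an estimated correlation), with ITGAX at log2 -4.08 ± 0.14. The counts in these 5 lists were the same when adjusted over the list alone, and so were those of every list below for which no second count is given.

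Signalling genes of cell movement were lower by smaller amounts. Genes of PI3K and G protein signalling had 5 of 35 risen and 23 fallen (median -0.38, camera adjusted p = 0.000444; adjusted p = 0.318 with an estimated correlation), including ARRB2 (-0.85 ± 0.04) and GNG2 (-2.47 ± 0.13). Of 44 genes of the actin cytoskeleton 9 rose and 23 fell, with a median of only -0.13 (camera adjusted p = 0.0223; adjusted p = 0.318 with an estimated correlation). CYFIP2, a part of the WAVE complex, was the clearest of them (-4.52 ± 0.16).

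NF-kB targets had 3 of 29 risen and 20 fallen (median -0.47, camera adjusted p = 0.000296; adjusted p = 0.452 with an estimated correlation), with IL1B at -3.76 ± 0.16 and ICAM1 at -2.58 ± 0.14. Cytokines and chemokines had 6 of 31 risen and 14 fallen, or 5 and 14 adjusted over the list alone (median -0.47, or -0.27 with 3 members at their bounds; camera adjusted p = 0.0359; adjusted p = 0.452 with an estimated correlation). CCL2, which attracts monocytes, fell from 94.3 ± 17.8 to 2.14 ± 0.466 CPM, and CXCL8 from 112 ± 18 to 24.8 ± 0.493 CPM. The call on the cytokine list was lost with total-count scaling (0.0615) and without any 1 of the 6 vector libraries (0.0682 to 0.0924). Apoptosis regulators had 5 of 24 risen and 15 fallen (median -0.32, camera adjusted p = 0.0315; adjusted p = 0.318 with an estimated correlation), among them BCL2A1 (-4.10 ± 0.20) and MCL1 (-0.66 ± 0.04).

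Cell cycle genes rose together. Of 41, 40 rose and 0 fell, or 41 and 0 adjusted over the list alone (median 0.91, camera adjusted p = 1.26e-06; adjusted p = 0.452 with an estimated correlation). MCM7, a subunit of the replicative helicase, rose from 296 ± 13.7 to 634 ± 45.0 CPM, and cyclin E1 (CCNE1) from 13.2 ± 1.06 to 26.2 ± 1.22 CPM. Markers of proliferating promyelocytes and progenitors had 12 of 14 risen and 0 fallen (median 0.82, camera adjusted p = 0.00413; adjusted p = 0.452 with an estimated correlation), including NCL (0.74 ± 0.10) and STMN1 (0.84 ± 0.14). Genes of mitochondrial translation had 38 of 42 risen and 1 fallen (median 0.51, camera adjusted p = 7.39e-08; adjusted p = 0.388 with an estimated correlation), such as MRPS34 (0.60 ± 0.05). Nuclear genes of oxidative phosphorylation had 37 of 46 risen and 3 fallen (median 0.40, camera adjusted p = 2.55e-07; adjusted p = 0.318 with an estimated correlation), such as CYC1 (0.74 ± 0.06). Cholesterol synthesis had 20 of 24 risen and 3 fallen, or 20 and 4 adjusted over the list alone (median 0.50, camera adjusted p = 0.00198; adjusted p = 0.42 with an estimated correlation). FDPS rose by 0.60 ± 0.07, while the sterol transporter STARD4 fell by 0.53.

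Cytosolic ribosomal proteins had 35 of 54 risen and 5 fallen, or 36 and 5 adjusted over the list alone (median 0.17, camera adjusted p = 0.00019; adjusted p = 0.493 with an estimated correlation), with RPL8 at 0.57 ± 0.05. The unfolded protein response (17 of 22 risen, 4 fallen, median 0.28, camera adjusted p = 0.0315; adjusted p = 0.452 with an estimated correlation) was called higher as a list, although DNAJC3 fell by 0.66. Amino acid and integrated stress response genes had 22 of 37 risen and 8 fallen (median 0.29, camera adjusted p = 0.0328; adjusted p = 0.318 with an estimated correlation). In this list SLC7A5, an amino acid transporter, rose by 0.96 ± 0.07 and CEBPB fell by 1.15. Its call was lost without miR-722 -DOX replicate 3 (0.0558). The other 12 lists were not called. Primary granule proteins had 8 of 16 risen and 3 fallen (camera adjusted p = 0.433), with BPI at -2.68 ± 0.14 and AZU1 at 0.67 ± 0.12. The interferon response had 12 of 42 risen and 6 fallen, or 9 risen adjusted over the list alone (camera adjusted p = 0.133, and 0.00219 without vector +DOX replicate 2). Among 16 monocyte and macrophage markers 5 rose and 5 fell, IRF8 from 116 ± 10.4 to 269 ± 16.7 CPM and FCN1 by log2 -5.03 ± 0.27, and the median (0.39) and the mean (-0.62) differed in sign. Without both libraries that stood apart, more members of several lists rose: 30 of the interferon response (8 fell), 12 of the primary granule proteins (4 fell), 15 of the actin cytoskeleton (25 fell), 8 of PI3K and G protein signalling (24 fell), 6 of the integrins and adhesion molecules (16 fell), 3 of the phagocytic receptors (22 fell) and 7 of the monocyte and macrophage markers (4 fell).

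In total 10260 of 14682 genes changed (5405 rose and 4855 fell; 10604 at an unadjusted p under 0.05), and the median of all genes was 0.06. Which direction led depended on the processing: 4831 rose and 5312 fell with total counts, 4624 and 4873 with only the 2 groups compared, and 4597 to 4902 and 5263 to 5361 without any 1 of the 6 vector libraries. Large changes were mostly falls: 2006 genes fell and 569 rose by at least 2-fold. Without both libraries that stood apart, 11340 genes changed, and 2198 fell and 1312 rose by at least 2-fold. Leaving out miR-722 -DOX replicate 3 alone gave 1270 such rises. Among genes picked by size of change, KCNJ15 (ENSG00000157551.17, chromosome 21, 38157034 to 38307357), a potassium channel, fell from 31.9 ± 6.59 to 0.0605 ± 0.0327 CPM (log2 -8.98 ± 0.32, adjusted p = 1.53e-09). LRP1, an endocytic receptor, fell from 219 ± 48.2 to 3.43 ± 0.988 CPM, and the myosin MYO1D by log2 -8.16 ± 0.31. HOXC10 had 932 counts without DOX and 2 with it, a ratio of 423 (95% counting interval 117 to 3490). The highest rises were far smaller, CGREF1 at 1.64 ± 0.28, FAM81A at 1.51 ± 0.15 and the neuropeptide gene GAL at 1.48 ± 0.27.

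**Figure D2:**
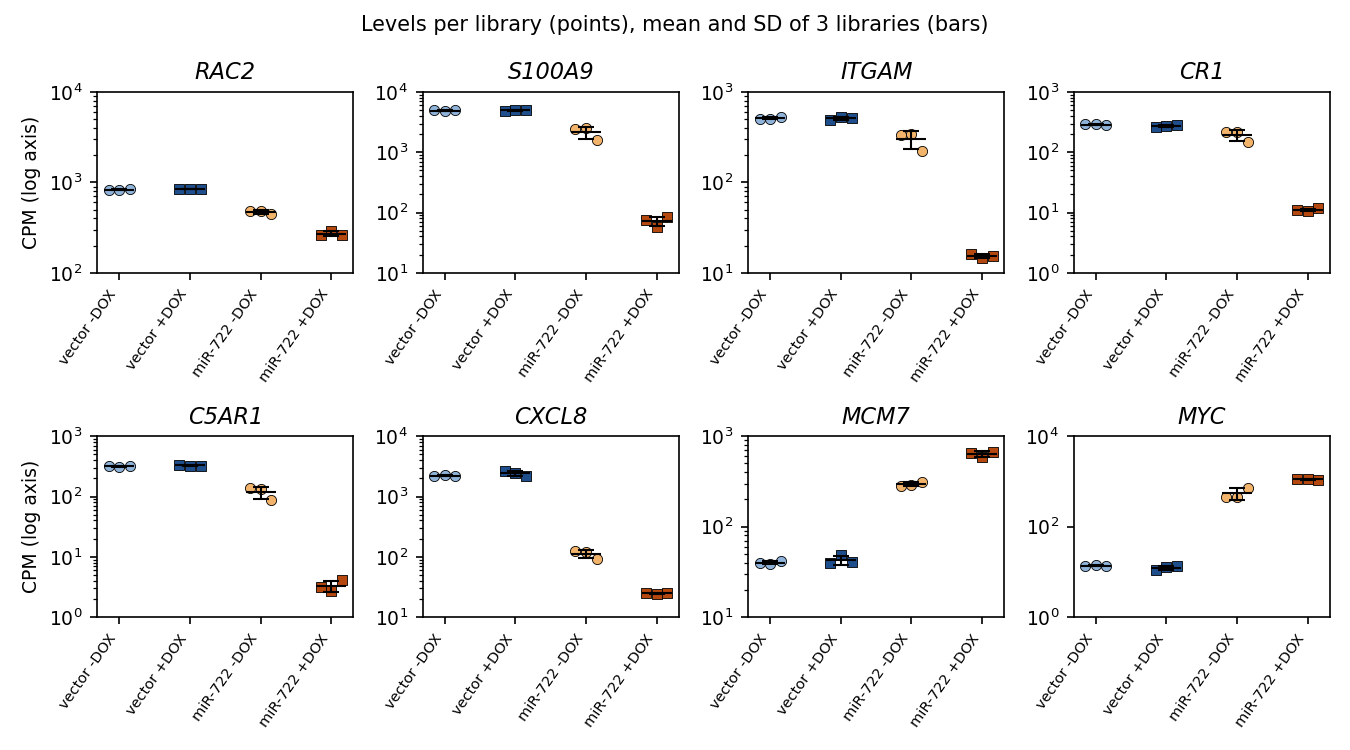
Level in CPM (log axis) of 8 genes in each library (points), with the mean and SD of the 3 libraries of each group (bars). RAC2, S100A9, ITGAM, CR1, C5AR1 and CXCL8 are lowest and MCM7 and MYC highest in miR-722 +DOX, and each miR-722 -DOX mean lies between the vector means and the miR-722 +DOX mean.

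RAC2 (ENSG00000128340.14, chromosome 22, 37225261 to 37244448, minus strand) encodes the Rac GTPase of blood cells, which neutrophils need to move, and was followed in every comparison as a target of miR-722 in zebrafish. It fell from 471 ± 19.4 to 271 ± 15.3 CPM on induction (SD, n = 3; log2 -0.80 ± 0.04, adjusted p = 2.28e-08). In the vector line it stood at 831 ± 7.48 CPM without and 840 ± 3.37 CPM with DOX (0.02 ± 0.04, adjusted p = 1.0). RAC2 was thus already lower in the miR-722 line before induction (-0.82 ± 0.04, adjusted p = 8.3e-09), and with DOX in both lines the difference was -1.63 ± 0.05 (adjusted p = 9.48e-12). Its response to DOX differed between the lines by -0.81 ± 0.06 (adjusted p = 8.03e-07). The annotated 3' UTR of RAC2, 781 bases long, held 1 copy of GCAAAAA, the complement of bases 2 to 8 of miR-722 as recalled from general knowledge.

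The comparison of vector +DOX with vector -DOX asked what doxycycline did to cells without the microRNA. By edgeR 0 of 14682 genes changed, with 543 at an unadjusted p under 0.05. DESeq2 gave 0 with 531, and edgeR with the replicate number as a block within each line gave 7. The NF-kB targets were slightly higher as a list (median 0.11, camera adjusted p = 2.21e-06; adjusted p = 0.776 with an estimated correlation), with 0 of 29 members called, TNFAIP3 at 0.13 ± 0.05 and SOD2 at 0.15 ± 0.06. Without vector +DOX replicate 1 this call was lost (0.07). Interferon response genes (median 0.38, camera adjusted p = 2.04e-07; adjusted p = 0.776 with an estimated correlation) and cell cycle genes (median 0.39, camera adjusted p = 2e-09; adjusted p = 0.776 with an estimated correlation) were higher only with vector +DOX replicate 2 included. Without that library both lists turned lower and uncalled (0.614 and 0.919), and ribosomal proteins were called higher (1.89e-06). Without replicate 1 ribosomal proteins were instead called lower (0.0417), and primary (0.00753) and secondary and tertiary granule proteins (0.0417) higher. The antiviral gene MX1 read 27.0 CPM in replicate 2 and 0.174 and 0.189 CPM in replicates 1 and 3, against 0.207 ± 0.0248 CPM without DOX. CCNA2, a cyclin of S phase and mitosis, stood at 11.7 ± 7 against 6.83 ± 0.434 CPM.

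**Figure D3:**
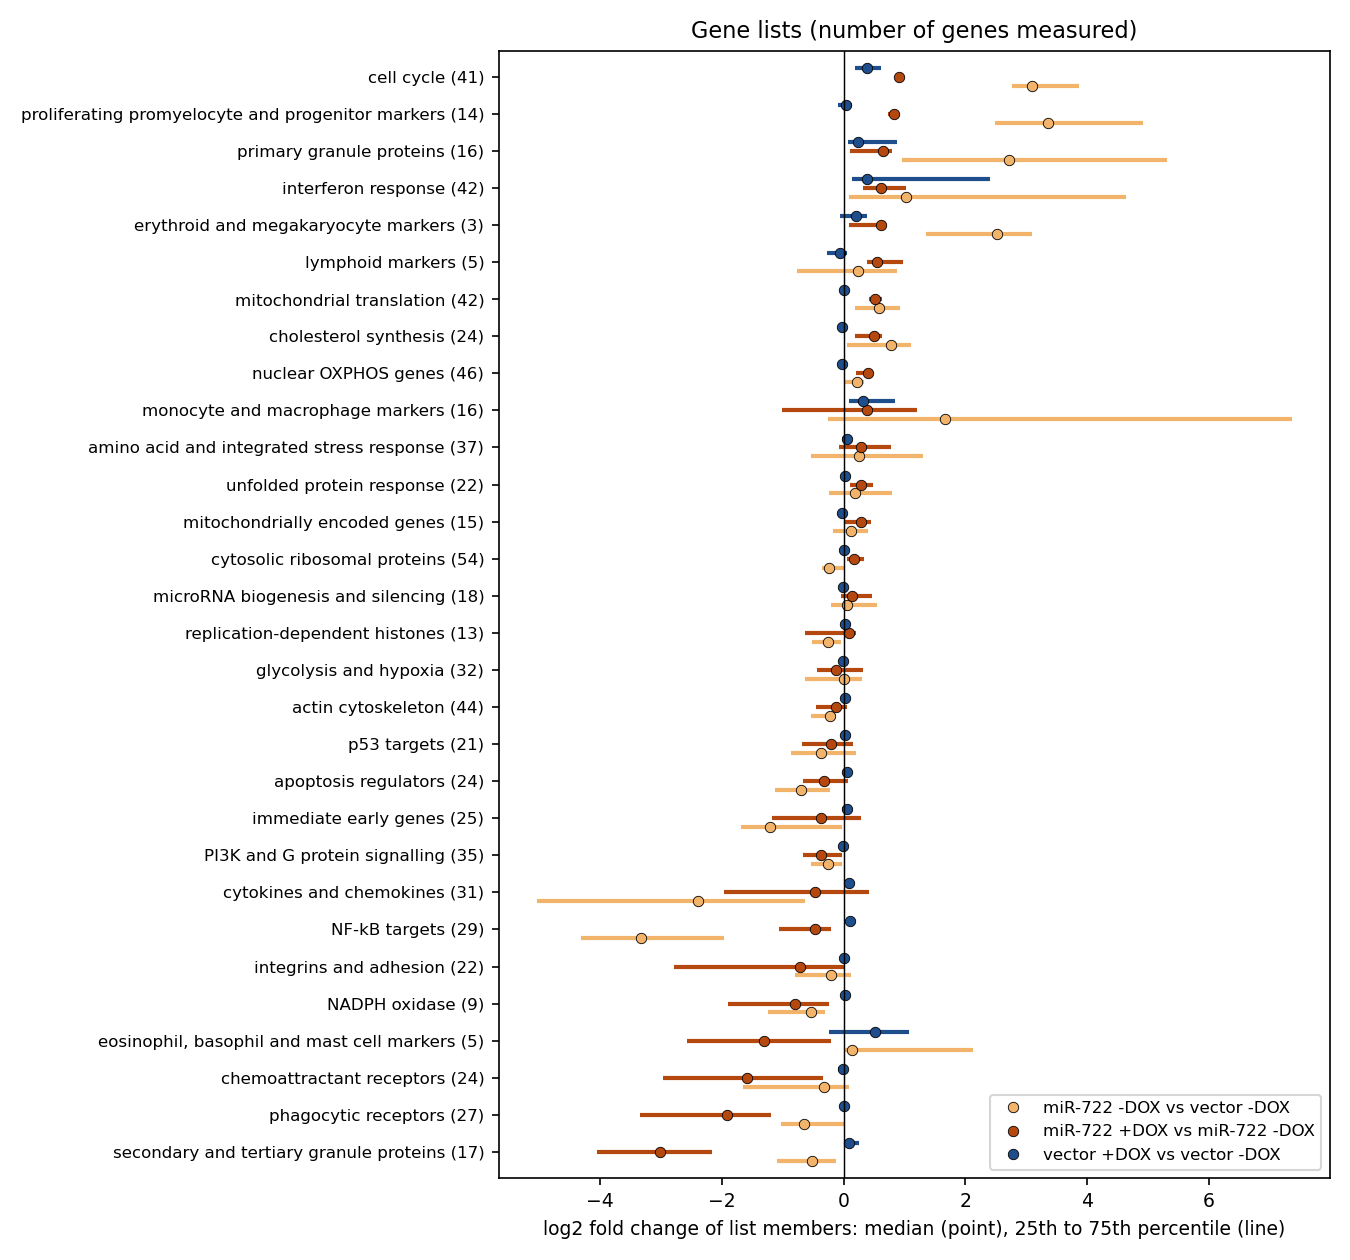
Median log2 fold change (points) and its range from the 25th to the 75th percentile (lines) over the members of each gene list drawn, for 3 comparisons; the number of genes measured follows each name. Secondary and tertiary granule proteins reach -3.01 on induction, while cell cycle genes reach 3.10 and NF-kB targets -3.33 in the miR-722 line against the vector line without DOX.

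The comparison of miR-722 -DOX with vector -DOX asked how far the lines differed before induction. Of the 31 gene lists, 7 were called higher and 11 lower in the miR-722 line with the preset correlation, and 1 with estimated correlations. MYC stood at 545 ± 158 against 13.7 ± 0.257 CPM (log2 5.31 ± 0.18, adjusted p = 1.86e-10). MPO (ENSG00000005381.7, chromosome 17, 58269856 to 58280935), the myeloperoxidase of primary granules, stood at 4220 ± 2460 against 67.6 ± 1.08 CPM (5.96 ± 0.35, adjusted p = 1.72e-08). CCL3 (ENSG00000277632.1, chromosome 17, 36088256 to 36090169), an inflammatory chemokine, stood at 2.31 ± 0.218 against 107 ± 1.35 CPM (-5.53 ± 0.08, adjusted p = 7.68e-13).

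All 41 cell cycle genes were higher (median 3.10, camera adjusted p = 2.16e-14; adjusted p = 0.467 with an estimated correlation), MCM7 by 2.88 ± 0.08 and CCNE1 by 3.40 ± 0.13. All 14 progenitor markers were higher (median 3.35, camera adjusted p = 8.48e-06; adjusted p = 0.467 with an estimated correlation), among them the receptor kinase FLT3 (70.7 ± 23.0 against 1.42 ± 0.423 CPM). Primary granule proteins had 13 of 16 higher and 2 lower (median 2.72, camera adjusted p = 0.00492; adjusted p = 0.495 with an estimated correlation), with the protease PRTN3 at 8.67 ± 0.35. Mitochondrial translation (32 of 42 higher, 2 lower, median 0.58, camera adjusted p = 7.71e-06; adjusted p = 0.495 with an estimated correlation) and cholesterol synthesis (16 of 24 higher, 4 lower, median 0.77, camera adjusted p = 0.00726; adjusted p = 0.495 with an estimated correlation) were higher. NF-kB targets were the lowest list, with 0 of 29 higher and 27 lower (median -3.33, camera adjusted p = 1.71e-14; adjusted p = 0.251 with an estimated correlation). TNFAIP3, an inhibitor of this pathway, stood at 55.1 ± 0.587 against 366 ± 6.88 CPM. Cytokines and chemokines had 6 of 31 higher and 24 lower (median -2.39, camera adjusted p = 4.51e-06; adjusted p = 0.251 with an estimated correlation), with CCL4 at -6.10 ± 0.12 and CCL22 at -5.57 ± 0.12. Immediate early genes had 3 of 25 higher and 17 lower (median -1.21, camera adjusted p = 0.000387; adjusted p = 0.209 with an estimated correlation), such as IER3 (-5.12 ± 0.11) and BTG2 (-4.03 ± 0.10). Of 44 actin cytoskeleton genes 1 was higher and 33 lower (median -0.23, camera adjusted p = 7.56e-06), and this list was also called with an estimated correlation (adjusted p = 0.0226). The crosslinker FLNA stood at 1640 ± 97.5 against 4500 ± 104 CPM and LCP1 at 2420 ± 129 against 4620 ± 15.9 CPM. Phagocytic receptors had 4 of 27 higher and 18 lower, or 7 and 18 without both libraries that stood apart (median -0.65, camera adjusted p = 0.00929; adjusted p = 0.606 with an estimated correlation). The NADPH oxidase had 2 of 9 higher and 7 lower (median -0.53, camera adjusted p = 0.046, and 0.0552 without vector +DOX replicate 1; adjusted p = 0.495 with an estimated correlation). Among markers of other cell types, not called as lists, 10 of 16 of monocytes and macrophages were higher and 4 lower (median 1.66, camera adjusted p = 0.0827), and 2 of 3 of erythroid cells and megakaryocytes were higher and 0 lower (median 2.51, camera adjusted p = 0.12).

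In this comparison total counts in place of TMM moved the median of all genes by 0.20, and moved the share of changed genes that were higher from 50.7 to 66.5%. Ribosomal proteins (10 of 54 higher, 36 lower, or 11 and 36 adjusted over the list alone, median -0.24, camera adjusted p = 0.00361; adjusted p = 0.647 with an estimated correlation) were not called with total counts (0.0871). The interferon response (29 of 42 higher, 7 lower, median 1.03, camera adjusted p = 0.0422; adjusted p = 0.728 with an estimated correlation) was not called with total counts either (0.196), nor without any 1 of the vector -DOX libraries or miR-722 -DOX replicate 1 or 2 (0.0636 to 0.0907). Secondary granule proteins, not called here (0.0962), were called lower with total counts (0.0261).

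In number, 10504 of 14682 genes differed (5327 higher, 5177 lower), and 2521 were higher and 1094 lower by at least 2-fold. Without both libraries that stood apart the number was 10660. Some genes had 0 counts over the 3 vector libraries, and for these the fold is a lower bound at 3 counts over the group. ADGRA2 (6637 counts in the miR-722 line) was at least 2010-fold higher, DTNA at least 1570-fold and LAPTM4B at least 1420-fold. In the other direction stood TNFRSF18, a receptor of the TNF family (0.0625 ± 0.0128 against 18.6 ± 1.03 CPM), the cytokine subunit EBI3 (0.125 ± 0.0358 against 31.5 ± 1.01 CPM) and IL12B (log2 -7.28 ± 0.45).

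The comparison of miR-722 +DOX with vector +DOX set the lines side by side with DOX in both. Most differences seen without DOX were present again, and secondary and tertiary granule proteins and phagocytic receptors stood lower against the vector line than without DOX. CXCL8, the main neutrophil chemokine, stood at 24.8 ± 0.493 against 2440 ± 258 CPM (log2 -6.62 ± 0.13, adjusted p = 1.65e-12). S100A9 stood at 71.7 ± 13.1 against 4950 ± 32.2 CPM (-6.11 ± 0.19, adjusted p = 1.56e-11). MCM7 stood at 634 ± 45.0 against 42.9 ± 4.80 CPM (3.88 ± 0.08, adjusted p = 1.99e-12).

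NF-kB targets had 1 of 29 higher and 27 lower (median -4.15, camera adjusted p = 2.94e-10; adjusted p = 0.352 with an estimated correlation), with CD83 at -4.21 ± 0.07 and ICAM1 at -6.01 ± 0.16. Secondary and tertiary granule proteins had 0 of 17 higher and 16 lower (median -3.95, camera adjusted p = 0.000148; adjusted p = 0.352 with an estimated correlation), including the gelatinase MMP9 at -7.60 ± 0.20. Phagocytic receptors had 4 of 27 higher and 23 lower (median -3.23, camera adjusted p = 4.15e-05; adjusted p = 0.384 with an estimated correlation), and chemoattractant receptors 4 of 24 higher and 18 lower (median -3.41, camera adjusted p = 0.0025; adjusted p = 0.352 with an estimated correlation). FPR2 was lower by log2 -6.26 ± 0.19 and C5AR1 by -6.64 ± 0.18. Actin cytoskeleton genes had 2 of 44 higher and 35 lower (median -0.34, camera adjusted p = 5.79e-05), again called with an estimated correlation (adjusted p = 0.0445), with CYFIP2 at -5.05 ± 0.16 and VASP at -1.87 ± 0.06. All 41 cell cycle genes were higher (median 3.66, camera adjusted p = 1.85e-10; adjusted p = 0.352 with an estimated correlation), as were all 14 progenitor markers (median 3.65, camera adjusted p = 6.85e-05; adjusted p = 0.352 with an estimated correlation). Mitochondrial translation had 38 of 42 higher and 3 lower (median 1.07, camera adjusted p = 3.93e-07; adjusted p = 0.352 with an estimated correlation), MRPS34 by 1.8 ± 0.06. The number of genes that differed was 12548 (6322 higher, 6226 lower), and 12725 without both libraries that stood apart; without any 1 of the vector libraries more were lower (6364 to 6484) than higher (5890 to 6043). Total counts in place of TMM moved the median of all genes by 0.14. TERT, the catalytic subunit of telomerase, had 3509 counts in the miR-722 line and 0 in the vector line, at least 1040-fold higher, and the receptor kinase AXL was at least 416-fold higher. CCL22 (0.209 ± 0.112 against 195 ± 19.1 CPM) and IL1A (0.208 ± 0.0276 against 157 ± 16.1 CPM) were lower.

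The interaction asked which responses to DOX differed between the lines. Secondary and tertiary granule proteins had the lowest median of the lists, and all 17 were lower by this test (median -3.41, camera adjusted p = 5.53e-08; adjusted p = 0.297 with an estimated correlation). Of 27 phagocytic receptors 0 were higher and 22 lower (median -2.21, camera adjusted p = 1.05e-09; adjusted p = 0.299 with an estimated correlation), and of 24 chemoattractant receptors 2 were higher and 19 lower (median -1.68, camera adjusted p = 3.39e-05; adjusted p = 0.297 with an estimated correlation). CYFIP2 differed by -4.47 ± 0.20. Oxidative phosphorylation had 36 of 46 higher and 2 lower (median 0.42, camera adjusted p = 2.54e-08; adjusted p = 0.297 with an estimated correlation). Mitochondrial translation had 37 of 42 higher and 1 lower (median 0.51, camera adjusted p = 2.68e-08; adjusted p = 0.356 with an estimated correlation). Cell cycle genes were higher as a list (median 0.54, or 1.12 without both libraries that stood apart; camera adjusted p = 0.000277; adjusted p = 0.567 with an estimated correlation), with 13 of 41 members called, or 12 adjusted over the list alone, and 40 without both libraries. In all 7597 genes differed (3508 higher, 4089 lower), and 9343 (4840 and 4503) without both libraries. Leaving out 1 library at a time gave 2310 to 4607 higher and 3769 to 4590 lower. By at least 2-fold, 220 were higher (138 to 546 without 1 library) and 1900 lower, and without both libraries 864 and 2107.

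Across the 14682 genes, the miR-722 minus vector differences without and with DOX, which share no libraries, had a Pearson correlation of 0.842 and a Spearman correlation of 0.923. In both states 5099 genes were higher, against 2293.8 by chance, and 4781 lower, against 2195.3, while 61 were opposite. The DOX effects in the 2 lines had a Pearson correlation of 0.17 and a Spearman correlation of 0.236, and the former was 0.009 without vector +DOX replicate 2. Genes are not independent replicates, so none of these correlations carries a p-value. In 11780 protein-coding genes with an annotated 3' UTR, the 2094 with GCAAAAA differed from the rest on induction by log2 -0.021 ± 0.028 (t = -0.74, adjusted for UTR length and A+T share). This t ranked 12 of the 42 orderings of the same letters and 4676 of all 7-mers, and the lowest was ATTTATT (t = -4.73). In the vector line GCAAAAA ranked 1 of 42 (t = -1.27).

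The deposited calls on miR-722 +DOX against miR-722 -DOX listed 632 genes up and 1943 down at a false discovery rate under 0.01 and a change of at least 1.8-fold. Of these, 611 (96.7%) and 1938 (99.7%) changed the same way here. Over 14217 genes the deposited and recomputed log2 fold changes correlated at 0.9998. The deposited comparison of the vector groups held 0 genes at a false discovery rate under 0.05, with 0.751 as its lowest. Among the enrichment terms listed by the submitters, Cell cycle held 28 of the higher genes (4.76-fold) and Cytokine-cytokine receptor interaction 43 of the lower genes (3.18-fold).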

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

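The interaction test, the gene lists and the other splits of the samples were chosen before the data were examined, while the tests of shares in the last paragraph were chosen only after the result was seen.

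Responses to DOX that differed between the miR-722 and the vector line are set apart here because the difference itself was tested. The edgeR interaction called 7597 genes, and camera called 21 lists with the preset correlation and 0 with estimated correlations. Of the 21, the unfolded protein response, amino acid and integrated stress response, immediate early genes, mitochondrially encoded genes and cytokines and chemokines also lost their call without single libraries. The interferon response, not called here (camera adjusted p = 0.708), was called higher without vector +DOX replicate 2 (0.00206). Among the genes with the highest difference (log2, miR-722 minus vector) were PRLR, the prolactin receptor, at 2.37 ± 0.91 and the phospholipase PLCG1 at 1.71 ± 0.37, with MPP3 at 1.74 ± 0.58, FAM161A and RNF207 both at 1.73, and C16orf74 at 1.72. PRLR lost its call in 12 alternatives, and FAM161A, MPP3 and C16orf74 lost theirs in 5 or more. At the other end, KCNJ15 differed by -8.79 ± 0.38 and MYO1D by -8.08 ± 0.37. JAKMIP2 had 0 counts in miR-722 +DOX and was at least 136-fold lower there than in miR-722 -DOX, and CHIC1 at least 99.5-fold. HOXC10 and ADAMTSL5 had 2 and 1 counts, with ratios of 423 (117 to 3490) and 327 (58.4 to 13000). RAC2 differed by -0.81 ± 0.06.

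Among 100 groupings drawn for the interaction, the real one included, 6 gave at least 7597 genes, the real value, with 8464 as the highest other, so chance is not excluded by this count. Genes were called in only 9 of the draws, the real one included, and these all kept the miR-722 libraries in their groups. Those 9 draws keep the difference between the miR-722 groups, so they do not measure chance. The draws that mixed the miR-722 libraries gave at most 0. Mixing groups that differ this much widens the spread within groups, so these draws could hardly give calls and decide nothing. For the pairwise comparisons 10 splits are too few for a share under 0.05. The real values and the highest others were 10260 and 0 for the miR-722 line (1 of 10 splits as large), 0 and 0 for the vector line (10 of 10), 10504 and 0 for the lines without DOX (1 of 10), and 12548 and 0 for the lines with DOX (1 of 10).

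The read summary, outside the main measurement, held shares of reads for which the libraries of a group all lay above the 9 others. In miR-722 +DOX, reads over splice junctions made up 25.1% ± 0.0654 (SD, n = 3; nearest other library 24.3%) and reads on the opposite strand of coding sequence 28.3% ± 0.151 (28.1%). Mitochondrial reads made up 5.21% ± 0.106 there (5.04%) and promoter reads 0.269% ± 0.00314 (0.253%). In miR-722 -DOX, reads of other exons made up 2.15% (2.08%), and in vector +DOX reads on the sense strand of 3' UTRs 0.43% (0.421%). Other shares lay below those of the 9 others, which the rule does not flag. In miR-722 +DOX these were reads on the opposite strand of other exons (21.7%, nearest other library 22.7%), of 3' UTRs (12.4%, 12.5%) and of 5' UTRs (0.86%, 0.936%), on the sense strand of 3' UTRs (0.327%, 0.343%) and of 5' UTRs (0.0432%, 0.0577%), and intergenic reads (3.3%, 3.4%). The share named as mapped to genes was lower in miR-722 -DOX (87.7%, 88.2%). Groups of 3 were not tested for single libraries that stand apart.

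The genes higher in miR-722 +DOX than in the vector line stood near a common share of that level in miR-722 -DOX, while the lower genes did not. Of 1847 genes at least 4-fold apart between miR-722 +DOX and the vector line, 98.5% had their miR-722 -DOX mean between the other means, and the 1054 higher ones stood at a median share of 0.42 (25th to 75th percentile 0.39 to 0.45) of the way up in replicates 1 and 2 and at 0.64 (0.58 to 0.69) in replicate 3. The relative spread of this share was 1.75 times that between the +DOX libraries (0.162 against 0.093), under a bound of 2 set after the result was seen. Cells or RNA of the +DOX kind as part of each miR-722 -DOX library thus stay possible but are not shown. A simulated mixture with counting noise alone gave a narrower spread, 0.063, which leaves out differences between libraries. The median log2 difference of all genes was 0.06, against 0.86 for this set. TMM scaling itself centres most genes between libraries, so a factor that lifts every gene could not be seen and stays untested. Vector RNA as the rest of each library is argued against by the 793 lower genes. Their share spanned 0.92, 0.90 and 0.59 from the 5th to the 95th percentile in miR-722 -DOX replicates 1, 2 and 3. In a +DOX library the span was at most 0.07, but the low level of these genes there narrows the share by construction. That test was first measured as a ratio of relative spreads (3.41), which decided nothing, and then in replicate 1 alone. A change of each gene by its own amount is left open by the ratio of 1.75, since the spread it would give was not measured. Simulated own shares drawn evenly from 0.1 to 0.9 gave 0.817, a value set by that chosen range, so it decides nothing. The ratio was first held against a bound of 2, which rested on no measured spread. In miR-722 -DOX the lower genes spread more widely (0.553) than the higher genes (0.162). Their spread in +DOX was 0.016, a ratio of 33.9. That ratio cannot be set against the 1.75, because the low level of these genes in +DOX narrows the share by construction. Also open is whether part of the uninduced culture, or more of the induced culture, remained undifferentiated. Another culture mixed in, or leaky expression of the microRNA that changed a part of the cells, stays open too. The microRNA was not measured and no undifferentiated library was analysed here. The falls of receptor, granule and oxidase genes on induction thus cannot be told apart from incomplete differentiation of the induced culture.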

How the results depend on the processing

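Leaving out both libraries that stood apart and applying the submitters' thresholds were tests chosen only after the data were seen; the other alternatives were set before the data were examined. The counts of changed genes stayed within 1.5-fold under DESeq2, its size factors, total counts, both filters, the replicate block and an adjusted p under 0.01. Requiring at least a 1.5-fold change gave 5419 genes for the induction, 6081 for the lines without DOX and 4192 for the interaction, and the submitters' thresholds gave 3033 for the induction, as stricter thresholds must. In the vector line the count was 0 in all alternatives but 1, the replicate block within line, which gave 7; the cause was not tested. Leaving out 1 library at a time gave 9158 to 11014 genes for the induction, 0 to 0 for the vector line, 9853 to 10526 for the lines without DOX, 12227 to 12815 for the lines with DOX, 6656 to 9060 for the interaction and 74 to 80 called lists. The replicate block over all groups gave 9967, 0, 10278, 12425 and 7189 genes. The replicate numbers did not pair the samples (own-number correlations across genes of 0.13, -0.25 and -0.17 in the miR-722 line and 0.02, 0.02 and -0.02 in the vector line). With estimated correlations 2 lists were called in place of 79. The r of the DOX effects in both lines ranged from 0.009 to 0.187 without 1 library, and that of the line effects from 0.824 to 0.909, the values 0.009 and 0.909 being those without vector +DOX replicate 2. The t of GCAAAAA went from -0.74 to 1.73 without covariates and to 0.03 with the interaction as response; the cause was not tested. Of the named genes, EPX reversed in miR-722 +DOX against vector +DOX, from an uncalled -0.16 to 6.69 without vector +DOX replicate 2 and 6.74 without both libraries; without 1 library at a time it ranged from -0.85 to 6.69. Over all named genes and alternatives, 13599 values kept their direction and side of the threshold, 91 lost their call, 17 gained one and 2 reversed. At this depth (30977995 to 36592278 counts per library) genes with 3 counts or fewer over a group allow only bounds or wide intervals.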

Other observations

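The tests on vector +DOX replicate 2 and on genes silent in vector -DOX were chosen only after the result was seen, whereas the test of GCAAAAA was set before the data were examined.

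Within the 12 lists not called on induction, several genes changed strongly. Mitochondrial transcripts went both ways: the ribosomal RNA MT-RNR1 fell from 702 ± 97.6 to 241 ± 7.86 CPM (SD, n = 3) and MT-RNR2 by 0.82 on the log2 scale, while MT-ATP6 rose from 2570 ± 111 to 3720 ± 94.9 CPM, and 10 of 15 mitochondrially encoded genes rose and 3 fell (camera adjusted p = 0.0586, and 0.0417 without miR-722 +DOX replicate 2). Of 32 genes of glycolysis and hypoxia 10 rose and 16 fell (0.236), with the glucose transporter SLC2A3 at 28.0 ± 0.13 against 298 ± 55.4 CPM and ENO2 at log2 -1.99 ± 0.11. Immediate early genes had 5 of 25 risen and 12 fallen (0.068, but 0.0485 without miR-722 -DOX replicate 3 and 0.0454 without both libraries that stood apart), among them JUN (-1.85 ± 0.10) and KLF6 (-1.64 ± 0.08). Of 21 p53 targets 6 rose and 10 fell (0.236), CDKN1A by log2 -0.77 ± 0.09. Genes of microRNA biogenesis and silencing had 10 of 18 risen and 4 fallen (0.236): the exportin XPO5 rose by 0.64 ± 0.06 and AGO4 fell by 0.59.

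Replication-dependent histones had 3 of 13 risen and 4 fallen (0.719), with a median of 0.09 and a mean of -0.16, and HIST1H2AC at -1.60 ± 0.16. Few markers of other blood lineages were measured. Among 5 lymphoid markers 2 rose, or 3 adjusted over the list alone, and 1 fell (0.647), CD4 from 514 ± 87.7 to 104 ± 5.5 CPM, a gene that monocytes also express. Of 5 eosinophil, basophil and mast cell markers 0 rose and 2 fell (0.271), CCR3 by log2 -3.63 ± 0.39 and CLC by -2.57 ± 0.51. Of 3 erythroid and megakaryocyte markers KLF1 rose by 0.69 ± 0.18 and EPOR fell by 0.43 (0.653).

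Genes silent in vector -DOX were also taken as a set. At or under 0.3 CPM in vector -DOX and at 5 CPM or more in every miR-722 library were 83 genes, 20 of them with 0 counts over vector -DOX, against 8 the other way round (CFAP46, EBI3, CCL24, TNFRSF18, MAMLD1, CCL1, KNDC1 and IL12B). Genes of MHC class II presentation were among the 83: CD74 stood at 359 ± 28.4 CPM in miR-722 -DOX and 827 ± 90.2 CPM in miR-722 +DOX, HLA-DRA at 25.2 ± 2.89 and 62.1 ± 6.43 CPM, and their regulator CIITA at 18.6 ± 0.327 and 41.6 ± 3.08 CPM. CD74 was not silent in vector +DOX replicate 2, where it read 13.8 CPM, while HLA-DRA read 0.338 and CIITA 0.203 CPM. In vector +DOX replicate 2, 29 of the 83 genes were at 1 CPM or more, and in replicate 1 or 3 there were 0. Over the 83 genes the miR-722 -DOX level was a median 48.6% of the +DOX level (25th to 75th percentile 44.4 to 52.3%, against 72.8 to 118.9% for all genes). This is not particular to the silent genes. The 1054 genes higher in miR-722 +DOX than in the vector line stood at median shares of 0.42 in miR-722 -DOX replicates 1 and 2 and 0.64 in replicate 3. Loss of chromosome segments in the vector line is argued against, since 0% of the 77 silent protein-coding genes had a silent expressed neighbour, with a mean of 1.29 and at most 12 in 10000 random placements. Other differences between the lines, such as selection of clones or silencing of single genes, were not tested and stay open.

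In vector +DOX replicate 2, 28 genes were on that the other 5 vector libraries lacked or held at a low level, and 25 of them were also on in every miR-722 library. They held 10 of the 42 measured genes of the interferon list, such as IFIT1 at 29 CPM, MX1 at 27 CPM and RSAD2 at 18.3 CPM, beside CD44 at 37 CPM and DYSF at 31.9 CPM. RNA of the miR-722 +DOX cultures mixed into this library may be argued against. The share it would need, taken from miR-722 +DOX levels, ranged from 0.116% to 12.1% between the 10th and 90th percentiles of 31 genes, a ratio of 105. No share was computed from miR-722 -DOX levels, so RNA of those cultures was not tested. A response of the whole vector line to DOX is argued against by 33 genes chosen from replicate 2 and vector -DOX alone. Higher by a median log2 of 3.72 in replicate 2, they differed from vector -DOX by a median of 0.0 in replicates 1 and 3 (at most 0.34); this test was first run on the 28 genes, which were chosen to be low in those replicates. A response of this culture alone, or cells of another kind, could not be tested with a single library.

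A direct action of the microRNA through GCAAAAA could be seen as lower levels of genes that carry it. Its t of -0.74 ranked 12 of 42 orderings, between the bounds set beforehand, and in the vector line, where the microRNA is absent by design, it ranked 1 of 42 (t = -1.27). In the interaction, the DOX effect particular to the miR-722 line, it ranked 35 of 42 (t = 0.03, log2 0.001 ± 0.03), which gives the site no support. An effect planted on shuffled fold changes of the vector DOX comparison ranked 1 and was recovered as log2 -0.17. The SE for GCAAAAA was 0.017 in the vector line and 0.028 on induction. Since the planting did not use the fold changes of the induction, it cannot show which effect sizes would be seen there. A direct action thus stays open, and the many changes of the induction could hide a small effect.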
